A study of Drosophila melanogaster with 3 samples.

How the data were processed

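ChIP-seq peak lists of Sp1-GFP from 3 biological replicates of whole wandering larvae were analysed, together with the list called on the 3 replicates pooled and the optimal set. Per the deposited text descriptions, each replicate list was made from that replicate's alignment and 1 control alignment, the pooled list from all 3 alignments and the control, and the optimal set from the 3 replicate lists and the pooled list by the irreproducible discovery rate (IDR). The assembly is dm6, per the labels. The aligner, the peak caller and their versions are not given in the sources used here.

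The lists are in narrowPeak format. The deposited signal of each peak is the authors' caller's own signal value, relative to the control, with no stated scaling between lists, so signals were used to rank peaks within a list and to show the spread of replicates, not to compare amounts of binding. The deposited −log10 q value reached its ceiling in 36.9% of pooled peaks and in 39.6%, 45.0% and 22.5% of the peaks of replicates 1, 2 and 3, and it was not used for ranking. The summit offset gave the position of each peak. The columns for score and p hold 1 constant each and were not used. The lists of the replicates and of the pool each end at 30000 lines. The optimal set was found to be the 8001 strongest peaks of the pooled list by signal, with a lowest signal of 220.4 and a median width of 390 bp, and 453 of its lines repeat an interval with another summit. The lists hold no read counts, so depth per library is unknown, and no interval or floor that needs it is given. Wilson intervals below cover the counting of peaks or genes only.

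Gene models were those of Ensembl release 115 (BDGP6.54, FlyBase 6.54) and sequence was Release 6 of the reference genome, whose coordinates are those of dm6. Every peak end lay within the length of its chromosome arm in that sequence. Peaks on 2L, 2R, 3L, 3R, 4 and X were used, with 13945 protein-coding genes and 19607 TSSs. Transposable element records were left out. Two-sided tests were used throughout. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the computations.

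Each replicate was represented by its N strongest peaks, with N the 8001 peaks of the optimal set, and a site was shared when summits lay within 100 bp. Chance overlap came from 100 circular shifts of summits along each arm (seed 1). A replicate's signal at an optimal peak was that of its highest peak with a summit within 100 bp. A promoter was 500 bp either side of a protein-coding TSS. Locations were assigned in the order promoter, 5' UTR, coding exon, 3' UTR, intron, other transcribed and intergenic. The background was the 19663 pooled summits farther than 500 bp from every optimal summit, which could have passed the threshold and did not. Location classes, gene lists and sequence words were tested with Fisher's exact test and Benjamini-Hochberg adjustment within each of these 3 families, with a threshold of 0.05. Gene lists were compared with all other protein-coding genes. Of 355 symbols in explicit lists, 6 matched under an older name, and 3 (Dl, d and Tor) were left out because their older symbol belongs to more than 1 gene. Other lists were taken by symbol pattern.

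Words were searched on both strands within 100 bp of summits. Background windows were drawn to the same numbers in bins of 5 percentage points of G+C content, which left 7714 of each. Spreads are the SD over the 3 replicates, analysed the same way on their own lists. Promoter and distal signal were compared by an exact sign-flip permutation test, which with 3 replicates cannot go below 0.25. With 1 group there is no comparison between conditions and no pairing of replicates. The replicates come from separate biosamples of 1 line, and their lists were checked for identity before use.

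Groups, tests, gene lists, words and the rule for named genes were fixed before the data were examined. The rule names Sp1 and the Sp/KLF family, the genes at the 20 strongest optimal peaks (by a TSS within 500 bp, else the gene body, else the nearest TSS), and, for each list past the threshold and for appendage patterning, ecdysone response and Polycomb and trithorax group genes, the 3 members with the highest promoter peak and up to 2 members without one, first by symbol. Alternatives changed the summit distance to 50 bp, the overlap rule, N, the promoter distance to 200, 1000 or 5000 bp, the background, the word window to 50 or 250 bp and the peak set, and left out each replicate in turn. Location shares among summits outside promoters were added after seeing the data. Leaving out a replicate meant using the sites shared by the N strongest peaks of the other 2. For these sites and for the strongest 4001 optimal peaks, the background of promoters, location classes and words was redrawn. It was then the pooled summits farther than 500 bp from that smaller set, which can include optimal peaks.

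The statistics were tested on simulated data. With 28% of genes given a peak at random and 70% of the members of 3 lists in 20 runs, the gene list test on 13945 genes called 100% of planted lists and 1.52% of the others. Simulated genes received peaks independently, whereas real neighbours can share 1 peak, so these rates need not hold for the real lists. The planted lists, proteasome, muscle marker and chemoreceptor genes, had 48, 21 and 179 members. Recovery of shorter lists or of weaker differences was not simulated. The overlap measure on 8000 sites recovered 61.4% where 61.0% were planted. The word test on 6000 windows gave an odds ratio of 2.81 with GC boxes planted in 10% of windows and 1.03 with none planted.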

Results

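Chromatin bound by Sp1 was profiled in whole larvae of Drosophila melanogaster, wandering at the end of the third instar, with males and females pooled. Sp1 is a zinc finger transcription factor of the Sp/KLF family, known with its neighbour and relative btd for its role in the growth of legs and antennae. The larvae came from a transgenic line that carries Sp1 with green fluorescent protein at its C terminus, and DNA crosslinked to the fusion was recovered with an antibody to the tag (ChIP-seq) after sonication. The design has 1 group with 3 biological replicates, each from its own biosample of the same line, and no other genotype, stage or treatment. It therefore asks where the fusion was bound and how far replicates differ. The 3 replicate lists and the pooled list each held 30000 peaks, so their lengths carry no information, and the authors' optimal set held 8001 peaks. Read depth per library is unknown from these lists, and all peak heights below are the authors' signal values. Coordinates are in dm6, counted from 1.

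The 20 strongest sites of Sp1-GFP were found in every replicate, and 13 of them lay at promoters. The highest pooled signal, 11363, was 90 bp upstream of CG14100 (3L, peak 19590300 to 19590888), where the replicates had a signal of 3804 ± 798 (SD, n = 3). A nearly equal peak lay 162 bp upstream of Gapdh2, a glycolytic enzyme gene (X, 15867653 to 15868421), with 3786 ± 1415 (SD, n = 3). Of the 20 strongest optimal peaks, 13 had their summit within 500 bp of a protein-coding transcription start site (TSS), 4 lay in introns and 3 lay outside protein-coding genes. Such a majority did not hold farther down: promoters held 48.0% of the 1000 strongest optimal peaks and 43.1% of the next 1000, near the 44.5% of all. All 20 were among the 8001 strongest peaks of each replicate, and the median coefficient of variation of their signal over the replicates was 17.1%. Because the 20 were picked by signal pooled over these same replicates, their presence in each follows in part from the choice.

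Other promoters among the 20 belonged to Ugalt, a nucleotide sugar transporter gene, Fkbp14, which encodes a prolyl isomerase, mRpL41, Art3, gish, ph-p, PNPase, CG18549, CG1888, CG11309 and CG9147. The 4 intronic summits lay in CG11050, CG32772, ush and Lk6. The ush summit, 4851 bp downstream of a TSS, had a signal of 3384 ± 229 (SD, n = 3) and shares its interval (2L, 479443 to 482144) with a weaker summit 360 bp upstream of cbt. The remaining summits lay at 5019 bp from the TSS of CG4004, -5728 bp (upstream) from that of eEF1gamma and 11911 bp from that of CG13323. The Art3 summit also lies 139 bp upstream of the divergent gene mRpS10, so that 1 peak counts for both genes.

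Across all sites, 64.4% ± 6.95 (SD over 3 pairs) of the 8001 strongest peaks of a replicate had a summit within 100 bp in another replicate, against 1.22% when summits were shifted along the chromosome. Replicates 1 and 2 shared 70.9%, replicates 1 and 3 shared 65.1%, and replicates 2 and 3 shared 57.1%. Of the optimal peaks, 4162 (52.0%) were among the strongest peaks of all 3 replicates, 2471 of 2, 1262 of 1 and the remaining 1.32% of none. Spearman's rho of signal across optimal peaks was 0.727 ± 0.0817 (SD over 3 pairs), and peaks are not independent replicates. No pair was close to identical, so each list was counted as a replicate.

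Sp1-GFP summits were concentrated at promoters. Within 500 bp of a protein-coding TSS lay 44.5% of optimal summits (Wilson 95% interval 43.4 to 45.6), against 16.9% of the 19663 pooled summits farther than 500 bp from any optimal summit, an odds ratio of 3.93 (3.71 to 4.16; Fisher's exact test, two-sided, with a p too small to be represented). Promoters take up 11.5% of the sequence, and shifted optimal summits fell there in 11.4% of cases, at most 12.5% in 100 shifts. In the replicates the share was 44.8% ± 7.23 (SD, n = 3): 48.1% in replicate 1, 49.9% in replicate 2 and 36.5% in replicate 3, each above the background. Mean G+C content moved with this share, at 37.8%, 38.7% and 34.8% in replicates 1, 2 and 3.

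Coding exons were nearly free of strong peaks. They held 0.187% of optimal summits and 2.67% of background summits, although they make up 13.9% of the sequence (odds ratio 0.0685, adjusted p = 4.05e-58 by Fisher's exact test with Benjamini-Hochberg adjustment over 7 location classes). Introns held 36.0% against 50.1% and intergenic sequence 15.7% against 24.2%, but shares sum to 100%, so a higher promoter share lowers the others. Among the 4442 optimal and 16331 background summits outside promoters, a comparison chosen after seeing the data, introns held 64.8% against 60.3% (odds ratio 1.21, adjusted p = 1.09e-07 by Fisher's exact test over 6 classes; 65.0% ± 0.467 in the replicates, SD, n = 3). Coding exons (odds ratio 0.102, adjusted exact p = 2.15e-36) and the 3' UTR (0.632, adjusted p = 0.00119) were lower there. Intergenic sequence (0.963, adjusted exact p = 0.484), the 5' UTR (0.873, adjusted p = 0.531) and other transcribed sequence (1.02, adjusted p = 0.828) did not pass the test.

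**Figure D1:**
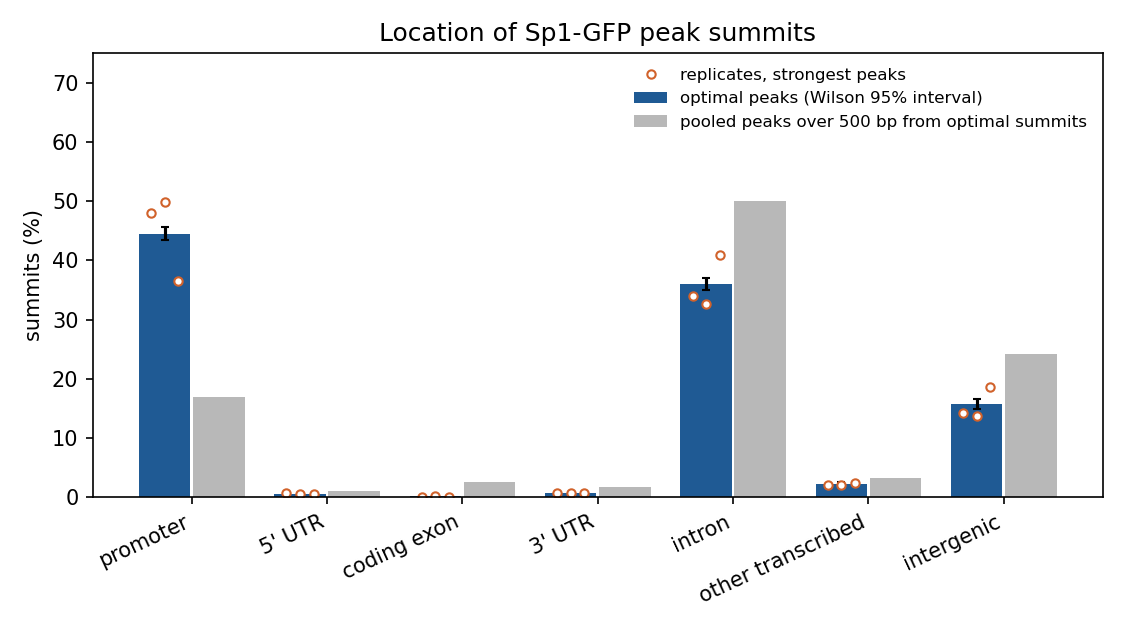
Share of peak summits (%, vertical axis) in 7 location classes for the 8001 optimal peaks (blue bars, Wilson 95% intervals) and for pooled peaks farther than 500 bp from optimal summits (grey bars), with the 8001 strongest peaks of each replicate as open circles. The optimal bar at promoters stands at 44.5% against 16.9%, and since the bars of each set sum to 100%, the higher promoter share lowers the other blue bars.

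Promoter summits sat just upstream of the TSS. Of the 3559 optimal summits at promoters, 68.2% (Wilson 95% interval 66.6 to 69.7) lay upstream of the nearest TSS, with a median offset of -69 bp, against 55.3% of background summits at promoters. The replicates gave 68.4% ± 6.15 (SD, n = 3), so that the difference from the background was larger than their spread. Promoter peaks were not detectably taller than the rest: their median signal over that of optimal peaks beyond 500 bp was 1.06 ± 0.121 (SD, n = 3), with 1.09 and 1.16 in replicates 1 and 2 and 0.927 in replicate 3. An exact two-sided sign-flip permutation test on the log2 ratios gave p = 0.5, and its smallest possible p with 3 replicates is 0.25.

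The gene for Sp1 had no optimal peak at its own promoter, while its neighbour btd had a modest one. The btd peak (X, 9693891 to 9694100) had its summit 196 bp upstream of the TSS, a pooled signal of 265 and rank 6688 of 8001, with 88.2 ± 10.1 (SD, n = 3) in the replicates. At the TSS of Sp1 the strongest pooled peak had a signal of 146, below the lowest optimal signal of 220. The gene body of Sp1 (X, 9729648 to 9756369) held 3 optimal summits in introns, at 9738695, 9742267 and 9747662, with pooled signals of 466, 463 and 458. These 3 summits were singled out after their values were seen. They and the btd peak lie in a region with many weak peaks, where a further copy carried by the tagged line stays open (see Other observations).

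**Figure D2:**
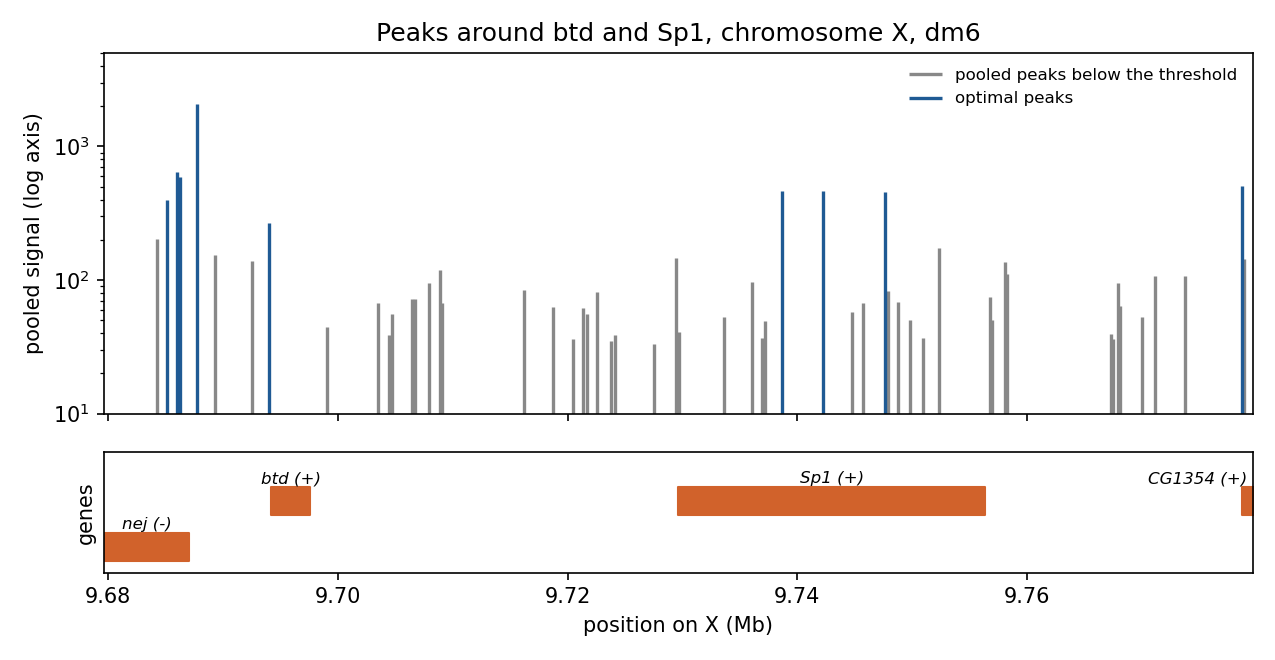
Pooled signal (log axis) of optimal peaks (blue) and of pooled peaks below the threshold (grey) at their summits in 100000 bp of chromosome X centred on the Sp1 TSS, with protein-coding genes below (position in Mb, dm6). The window holds 9 optimal summits, 3 of them inside Sp1, and 46 weaker ones.

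Elsewhere in the Sp/KLF family, cbt had a strong promoter peak, at rank 377 with 708 ± 67.4 (SD, n = 3). Spps, a family member known for its work with Polycomb group proteins, had a peak 81 bp upstream of its TSS (3R, 24226931 to 24227088), found in replicates 1 and 2 with signals of 159 and 112 and in no peak of replicate 3. The genes luna, dar1, hkb and Klf15 had no optimal promoter peak, though luna and dar1 had weaker pooled peaks there (162 and 186). The 3 of 8 members with a promoter peak did not differ from other genes (odds ratio 1.56, adjusted p = 0.751 by Fisher's exact test over 26 lists).

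In total 3873 of 13945 protein-coding genes (27.8%) had an optimal peak at the promoter. The strongest peaks of the replicates gave 3871 ± 498 genes (SD, n = 3), of which 2519 were found in all 3. Of 26 gene lists fixed before the data were examined, 9 had a peak more often than other genes, 5 less often, and 12 did not pass the test (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over the lists). Genes are not independent replicates, so these tests describe the lists. A gene counted when a peak lay at any of its TSSs. The number of TSSs per gene was not corrected for, so lists whose genes have more TSSs had more chances of a peak. Genes said below to have no promoter peak lack an optimal one. Some have a weaker pooled peak there, such as Asx (193), fj (193) and Dsor1 (191), below the lowest optimal signal of 220.

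Cytoplasmic ribosomal protein genes stood highest. Of 85 cytoplasmic ribosomal protein genes, 73 (85.9%) had a promoter peak, with an odds ratio of 16.1 (adjusted exact p = 1.16e-27) and 85.9% ± 1.18 in the replicates (SD, n = 3). RpS27 had a summit signal of 900 ± 51.5, RpL34b 808 ± 155 and RpL7 726 ± 74.5 (SD, n = 3 each), while RpL10 and RpL10Aa had no promoter peak. Of 73 mitochondrial ribosomal protein genes, 34 (46.6%) had one (odds ratio 2.28, adjusted exact p = 0.00254), among them mRpL41 with 2934 ± 788, mRpS10 with 2594 ± 426 and mRpS23 with 1944 ± 270 (SD, n = 3 each). mRpL1 and mRpL10 had none, and the call was lost without replicate 2 (odds ratio 1.72, adjusted exact p = 0.1005). Aminoacyl-tRNA synthetase genes had a peak in 14 of 32 cases (odds ratio 2.03, adjusted exact p = 0.0852) and proteasome genes in 16 of 48 (odds ratio 1.30, adjusted exact p = 0.574). The synthetase list passed the test in 5 of 12 alternatives, with up to 2.94 without replicate 3 (adjusted exact p = 0.00752).

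Genes of the EGFR, Hippo, Wnt and Notch pathways had promoter peaks more often than other genes. The EGFR list had 14 of 20 (odds ratio 6.09, adjusted exact p = 5.39e-04), with the secreted antagonist aos at 753 ± 22.5, the ligand spi at 703 ± 217 and the repressor cic at 307 ± 58.5 (SD, n = 3 each). Dsor1 and Sos had none. The Hippo list had 11 of 16 (68.8%, odds ratio 5.73, adjusted exact p = 0.00284), with Mer at 351 ± 18.5 and the kinase gene hpo at 205 ± 64.4 (SD, n = 3 each). For yki, the pathway's coactivator, a peak was found in 2 replicates, at 227 ± 16.2 (SD, n = 2). The cadherin gene ds and fj had no promoter peak, and the nearest optimal summit to a ds TSS lay 581 bp away. The Hippo call was lost on replicate 2 alone (odds ratio 2.40, adjusted exact p = 0.156), without replicate 2 (3.31, adjusted p = 0.0705) and with the strongest 4001 peaks (3.06, adjusted p = 0.0915), and the EGFR call with the latter (2.19, adjusted p = 0.229).

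The Wnt list had 14 of 24 (58.3%, odds ratio 3.65, adjusted exact p = 0.00525), led by the kinase gene sgg at 1093 ± 151, nkd at 434 ± 93.8 and the receptor gene fz3 at 256 ± 46.5 (SD, n = 3 each). Axn and Wnt10 had none. The Notch list had 12 of 23 (52.2%, odds ratio 2.84, adjusted exact p = 0.0338), with numb at 1314 ± 137, E(spl)m7-HLH at 925 ± 205 and E(spl)mdelta-HLH at 800 ± 31.9 (SD, n = 3 each), and no promoter peak at E(spl)m5-HLH or E(spl)m8-HLH. The Wnt share differed between replicates, at 58.3%, 45.8% and 29.2% in replicates 1, 2 and 3, and the call was lost on the strongest peaks of replicate 2 alone (adjusted exact p = 0.173) and of replicate 3 alone (adjusted exact p = 0.618), and without any 1 of the replicates. The Notch call was lost at 200 bp of a TSS (odds ratio 1.31, adjusted exact p = 0.754). It was also lost at 5000 bp (2.75, adjusted exact p = 0.0701) and without replicate 2 (2.74, adjusted p = 0.0807), where the odds ratio hardly moved.

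Ecdysone response genes and chromatin regulators were also high. Of 19 ecdysone response genes 12 (63.2%) had a promoter peak (odds ratio 4.47, adjusted exact p = 0.00389), and the replicates gave 68.4% ± 5.26 (SD, n = 3). The nuclear receptor gene Eip75B had 1090 ± 185, Ldh 1050 ± 125 and the transporter gene E23 1010 ± 359 (SD, n = 3 each). Hr38 had none, and the nearest optimal summit to Hr3 lay 504 bp from a TSS. Of 28 Polycomb and trithorax group genes 18 (64.3%) had one (odds ratio 4.70, adjusted exact p = 3.89e-04), with ph-p at 2327 ± 752, brm at 1462 ± 375 and E(z) at 844 ± 119 (SD, n = 3 each), and none at Asx or Caf1-55. The Polycomb and trithorax group call was lost without replicate 1 (odds ratio 1.98, adjusted exact p = 0.178) and without replicate 2 (2.37, adjusted p = 0.1005), and the ecdysone call with the strongest 4001 peaks (2.36, adjusted p = 0.221).

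Heat shock genes had a promoter peak in 14 of 27 cases (51.9%, odds ratio 2.81, adjusted exact p = 0.0195). Hsp27 was highest with 2110 ± 246, followed by Hsp83 with 1178 ± 465 and Hsc70-5 with 542 ± 112 (SD, n = 3 each), and Hsc70-1 and Hsc70-2 had none. The list includes near-identical Hsp70 copies, where reads shared between copies leave each call uncertain. The call was lost in 7 of 12 alternatives, among them replicate 3 alone (odds ratio 1.62, adjusted exact p = 0.392), 5000 bp of a TSS (1.65, adjusted p = 0.422), the strongest 4001 peaks (1.79, adjusted p = 0.292) and without replicate 2 (1.79, adjusted p = 0.329).

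Chemoreceptor, cuticle, cytochrome P450, Osiris and midgut enzyme genes had few promoter peaks. Only 2 of 179 chemoreceptor genes had one (1.12%, odds ratio 0.0289, adjusted exact p = 1.54e-21): Gr63a, with signals of 122, 159 and 23.7 in replicates 1, 2 and 3, and Ir60e, found in replicate 1 alone with a signal of 113. Gr10a and Gr10b had none. Of 92 cuticle protein genes of the CPR family 1 had a peak, Cpr12A at 103 ± 18.1 (SD, n = 3; odds ratio 0.0283, adjusted exact p = 4.22e-11), and Ccp84Aa and Ccp84Ab had none. Cytochrome P450 genes had 10 of 81 (12.3%, odds ratio 0.365, adjusted exact p = 0.00365), among them Cyp6u1 at 539 ± 91.5, Cyp310a1 at 292 ± 30.1 and Cyp6v1 at 292 ± 51.4 (SD, n = 3 each), and none at Cyp12a4 or Cyp12a5. Osiris genes had 1 of 23 (adjusted exact p = 0.0195), Osi24, found in replicate 3 alone, and none at Osi1 or Osi11. Midgut enzyme genes had 1 of 20 (adjusted exact p = 0.0413), zetaTry at 82.9 ± 27.4 (SD, n = 3). Amy-p and Amy-d, also without a peak, are near-identical copies and remain uncertain. The midgut call was lost at 200 bp of a TSS (adjusted exact p = 0.170), at 5000 bp (odds ratio 0.793, adjusted p = 0.857) and on replicate 1 alone (adjusted p = 0.0901), and the Osiris call on replicate 3 alone (odds ratio 0.307, adjusted p = 0.254). With the strongest 4001 peaks and without replicate 2, the calls were lost for Osiris genes (odds ratio 0 in both settings, adjusted exact p = 0.0692 and 0.0604) and for P450 genes (odds ratios 0.406 and 0.464, adjusted p = 0.0692 and 0.0860).

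Appendage patterning genes, the list closest to the known role of Sp1, had a promoter peak in 8 of 41 cases (19.5%), which did not pass the test (odds ratio 0.630, adjusted exact p = 0.427). The list was below other genes and passed with the strongest 4001 peaks (0.127, adjusted exact p = 0.0373) and without replicate 1 (0.123, adjusted p = 0.0318). With wider distances it was near other genes, at 0.913 within 1000 bp (adjusted exact p = 0.902) and 0.923 within 5000 bp (adjusted p = 0.960). These counts cover sites near a TSS only, so binding at distant sites of these genes was not assessed. The zinc finger gene bowl stood out at 1422 ± 74.7, while bi had 140 ± 56.2 and ptc 107 ± 46.6 (SD, n = 3 each), and B-H1 and B-H2 had none. Marker lists for muscle (4 of 21), neurons (4 of 20), fat body (6 of 17) and salivary gland (4 of 13) did not pass the test. Neither did neuroblast and temporal factors (8 of 26), Hox and homeotic genes (2 of 12), insulin and TOR pathway genes (10 of 22) or cell cycle and DNA replication genes (12 of 31). Of these, cell cycle genes passed at 5000 bp of a TSS (odds ratio 4.05, adjusted exact p = 0.00336), and without replicate 1 fat body markers (3.47, adjusted p = 0.0364) and insulin and TOR pathway genes (2.83, adjusted p = 0.0447) did.

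Against the 5936 genes with any pooled peak at the promoter, 2 of 26 lists passed in place of 14: ribosomal proteins stayed above other genes (odds ratio 13.2, adjusted p = 2.46e-09 by Fisher's exact test), and appendage patterning genes fell below them (odds ratio 0.176, adjusted p = 6.33e-05). In this comparison the odds ratios were 1.87 for the EGFR, 1.96 for the Hippo, 1.87 for the Wnt and 1.07 for the Notch list, 1.28 for ecdysone response genes and 1.92 for Polycomb and trithorax group genes, each lower by over 1.5 times. Those of heat shock genes (2.49), midgut enzymes (0.177) and cytochrome P450 genes (0.483) moved less, and their calls ended in a test on fewer genes. Chemoreceptors (0.266, adjusted exact p = 0.524), CPR cuticle proteins (0.133, adjusted p = 0.350), Osiris genes (0.533) and mitochondrial ribosomal proteins (1.51, adjusted p = 0.553) also moved towards 1 by over 1.5 times. Over all 12 alternative settings, the call held in 12 for ribosomal proteins, 11 for chemoreceptors and CPR cuticle proteins, 10 for the EGFR, ecdysone and mitochondrial ribosomal lists, 9 for Polycomb and trithorax group and P450 genes, 8 for the Hippo, Notch and Osiris lists and 5 for the Wnt, heat shock and midgut lists.

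**Figure D3:**
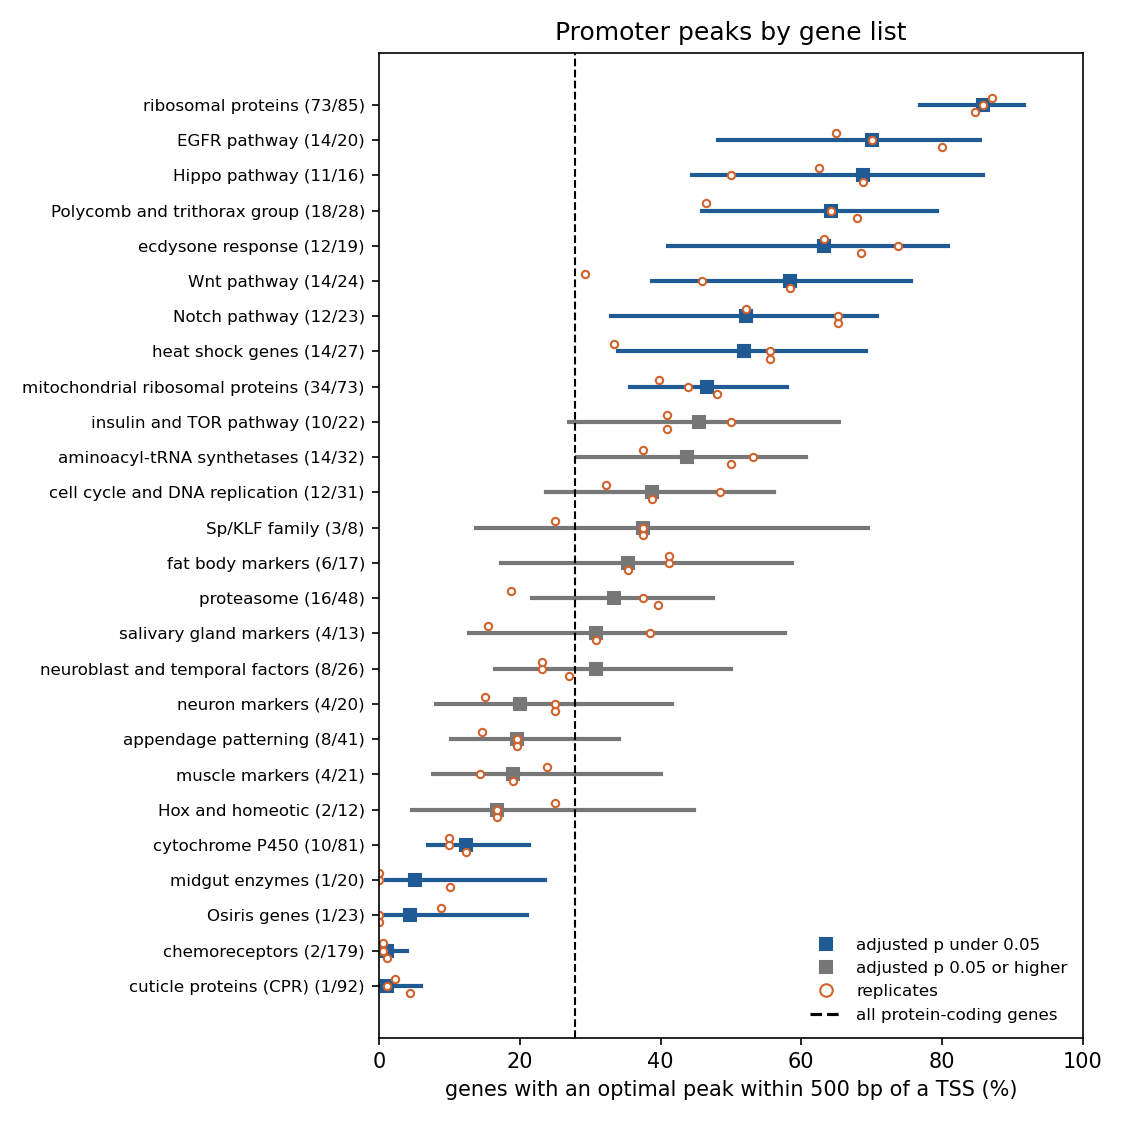
Share of each gene list with an optimal peak within 500 bp of a TSS (%, horizontal axis; squares with Wilson 95% intervals, counts beside the names), in blue where the adjusted p was under 0.05, with the replicates' strongest peaks as open circles. The dashed line is the 27.8% of all protein-coding genes; ribosomal proteins lie at 85.9% and CPR cuticle proteins at 1.09%.

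Sequence at the summits was poor in G and C. The GC box, the site that Sp family proteins are known to bind, was no more frequent there than at background summits of equal G+C content. The background holds weaker peaks of the same pull-down, and no unbound sequence of equal G+C content was compared. An excess shared by strong and weak peaks would therefore not be seen. Within 100 bp of optimal summits mean G+C content was 36.9%, against 42.1% at background summits, and signal fell with G+C content across optimal peaks (Spearman's rho -0.286; -0.260 ± 0.0444 in the replicates, SD, n = 3). GGGCGG or its complement lay at 4.45% of optimal summits and 4.76% of background summits of equal G+C content (7714 of each; odds ratio 0.932, 95% interval 0.799 to 1.09, adjusted p = 0.511 by Fisher's exact test over 19 words). The replicates gave an odds ratio of 0.967 ± 0.0829 (SD, n = 3). Without matching it was found at 4.30% against 7.65% of summits (odds ratio 0.542, unadjusted Fisher's exact p = 7.35e-26). The extended GC box RGGGCGK (odds ratio 0.900, adjusted exact p = 0.293) and the KLF word GGGTGTG (0.830, adjusted exact p = 0.190) also did not pass the test. Without matching, both passed below background (0.562, adjusted exact p = 1.78e-20, and 0.605, adjusted p = 7.96e-08).

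The strongest peaks were the poorest in G and C. In 8 groups of optimal peaks by falling signal, mean G+C content went from 32.5% in the strongest group to 39.8% in the weakest, and the share with a GC box from 3.0% to 6.49%, with a low of 2.5% in the group ranked next to the strongest. The TATA box word was found in 18.4% of the strongest group and in 9.89% of the weakest, and the Ohler 1 word in 0.300% and 2.60%. The homeodomain word TAATTA also fell, from 21.8% to 12.4%. These shares were not matched on G+C content, which differs between the groups, so they cannot be told apart from base composition.

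**Figure D4:**
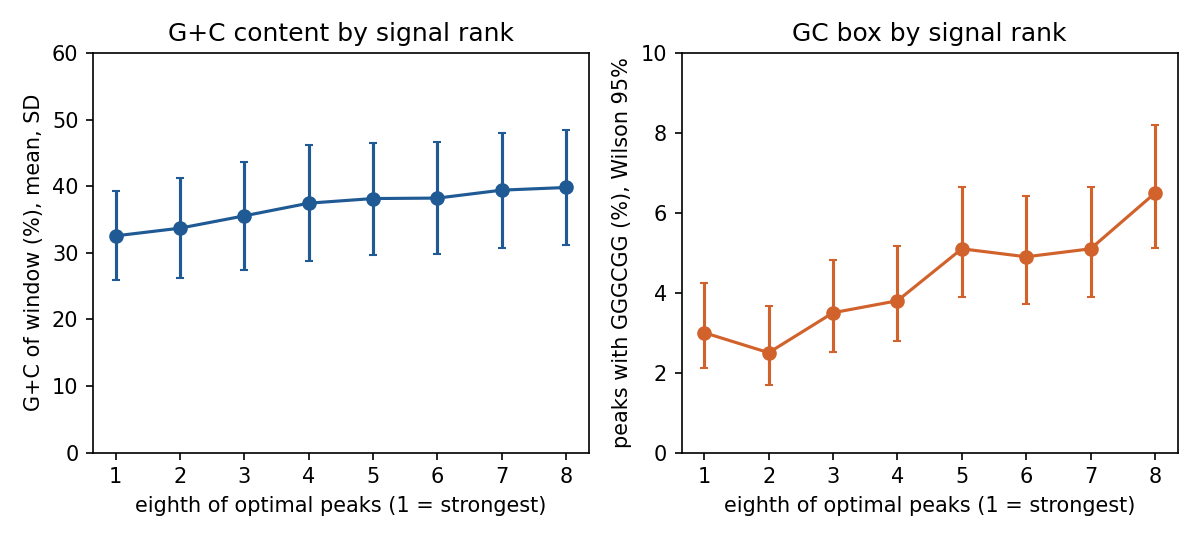
Left, mean G+C content of the 200 bp around optimal summits (%, with the SD over peaks) and right, share of optimal peaks with GGGCGG (%, Wilson 95% intervals), each in 8 groups of 1000 or 1001 peaks from the strongest (1) to the weakest (8). G+C content is 32.5% in group 1 and 39.8% in group 8.

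Words of other promoter factors were more frequent at Sp1-GFP summits than at background summits of equal G+C content. The core promoter word Ohler 1 (GGTCACACT), bound by M1BP, lay at 1.94% against 0.687% (odds ratio 2.87, adjusted exact p = 4.42e-11), the DNA replication-related element TATCGATA at 2.86% against 1.24% (2.34, adjusted exact p = 1.93e-11), Ohler 7 at 4.43% of optimal summits (1.81, adjusted exact p = 3.58e-10) and the GAGA word GAGAGAG at 5.21% against 3.38% (1.57, adjusted exact p = 1.16e-07). Each was above 1 in all 3 replicates. When background summits were also matched on promoter or distal location, the GAGA word (1.39, adjusted p = 7.37e-04) and Ohler 1 (1.42, adjusted p = 0.0392) passed Fisher's exact test, and TATCGATA (adjusted p = 0.568) and Ohler 7 (1.21, adjusted p = 0.114) did not. Without replicate 1 the odds ratio was 1.53 for Ohler 1 (adjusted exact p = 0.122) and 1.09 for TATCGATA (adjusted p = 0.825), and TATCGATA also lost its call without replicate 2 (1.21, adjusted p = 0.334) and with the strongest 4001 peaks (1.29, adjusted p = 0.223).

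Of the other words, 6 were less frequent at optimal summits: the Scalloped/TEAD word GGAATG (odds ratio 0.736, adjusted p = 3.20e-06), AP-1 (0.693, adjusted p = 0.00662), Pho (0.850, adjusted p = 0.0197), the initiator (0.919, adjusted p = 0.0221), Grainyhead (0.521, adjusted p = 0.0270) and GATA (0.862, adjusted p = 0.0270), by Fisher's exact test over 19 words. All of these were below 1 in each replicate, yet of 10 alternative settings the call held in 2 for AP-1, 3 for Grainyhead, 4 for Pho and the initiator, 5 for GATA and 7 for Scalloped/TEAD. Against flanks 1000 bp away, which were not matched on G+C content, the initiator (1.18, adjusted exact p = 5.47e-09) and GATA (1.16, adjusted p = 0.00886) were more frequent at optimal summits. The other 9 words, among them the TATA box (0.994), homeodomain (1.01), E-box, Zelda (0.867) and insulator CTCF (1.41) words and the reversed KLF control (0.956), did not pass. These calls rest on the matched background. Without matching on G+C content, homeodomain (1.52, adjusted exact p = 2.05e-26) and TATA box (1.64, adjusted p = 5.68e-31) words passed above background. The E-box (0.786, adjusted exact p = 0.0139), the reversed control (0.711, adjusted p = 3.43e-05), the extended GC box (0.562, adjusted p = 1.78e-20) and the KLF word (0.605, adjusted p = 7.96e-08) then passed below it. Against flanks, words that passed above included homeodomain (1.38, adjusted exact p = 7.12e-16), TATA box (1.75, adjusted p = 6.42e-37) and CTCF (1.55, adjusted p = 0.0151). Those that passed below included the E-box (0.803, adjusted exact p = 0.0263) and Zelda (0.657, adjusted p = 0.00767). G+C content within 50 bp of optimal summits was 0.813 times that at 150 to 250 bp. Without matching, the flank values of the other words named here therefore cannot be told apart from base composition. The CTCF word AGRKGGCGC is itself rich in G and C, so lower G+C content at summits would not raise it. With matching it did not pass (1.41).

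**Figure D5:**
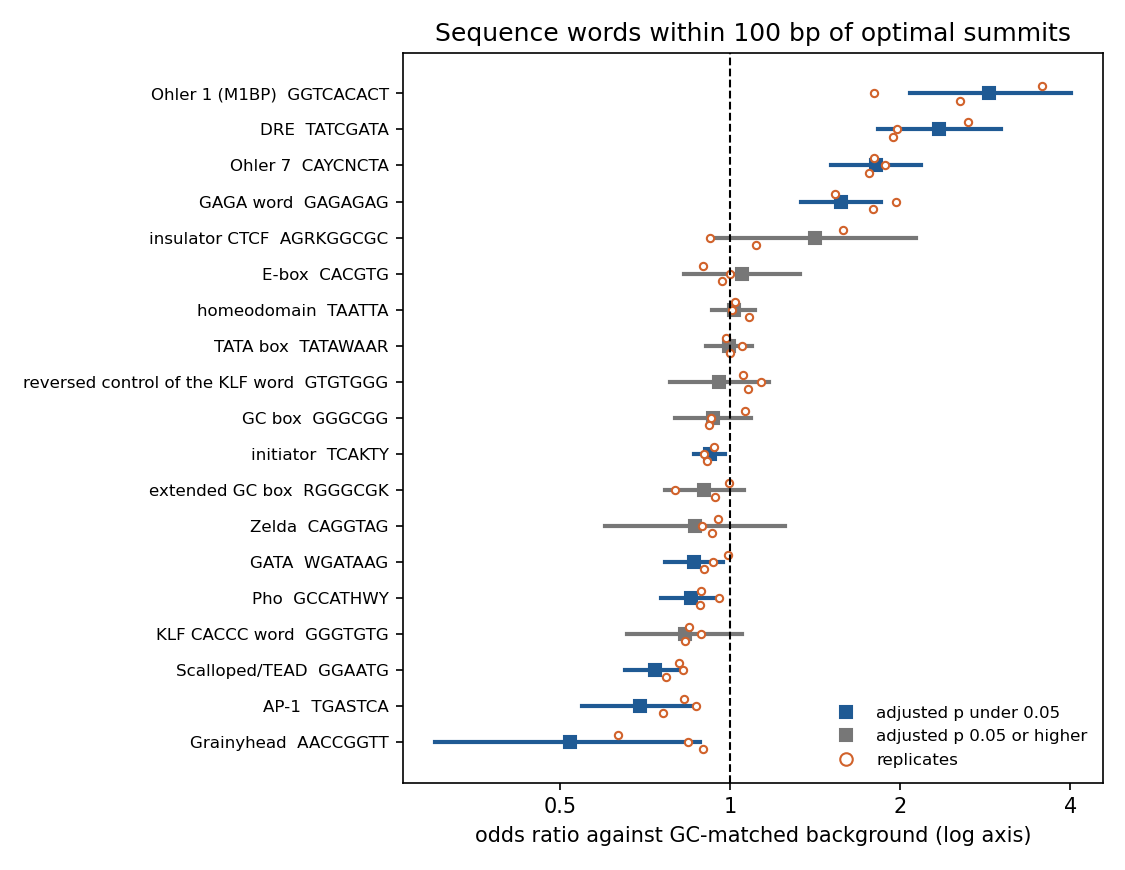
Odds ratio (log axis) of 19 sequence words within 100 bp of optimal summits against background summits of equal G+C content, with 95% intervals as bars, in blue where the adjusted p was under 0.05, and the replicates as open circles. Ohler 1, at 2.87, is highest, and the GC box, at 0.932, has an interval that includes 1.

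Chromosome X did not differ detectably from the pooled list in its share of optimal peaks. It held 19.6% of optimal peaks (Wilson 95% interval 18.7 to 20.5) and 19.9% of the pooled list, which includes them (odds ratio 0.980, p = 0.528 by Fisher's exact test), with 18.8% ± 0.992 in the replicates (SD, n = 3). X had 66.6 optimal peaks per Mb, against 55.8 to 62.9 on 2L, 2R, 3L and 3R and 8.16 on chromosome 4. Set against its 17.6% of the sequence, X held more optimal peaks (odds ratio 1.14, exact binomial p = 3.00e-06), and its genes had a promoter peak in 30.7% of cases (odds ratio 1.19 against the other arms, Fisher's exact p = 8.11e-04).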

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

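Alternatives were fixed before the data were examined, except 4 sets of tests chosen after seeing the data: overlapping peaks merged for location classes and for the GC box and other words, location classes outside promoters only, and pooled peaks beyond 500 bp of an optimal summit as the background for X (the same call, Fisher's exact p = 0.465). No paired analysis was possible because there is 1 group. The promoter odds ratio kept its call in every alternative (2.47 to 6.21), as did ribosomal proteins (9.42 to 24.5), and 43 of 48 location values were the same, 3 weaker and 2 reversed. Of 312 list values 222 were the same, 47 weaker, 11 stronger and 32 reversed; of 180 word values 108, 36, 10 and 26. Most reversed values are of lists or words that did not pass the test. Leaving out a replicate left 4571, 5212 or 5676 peaks, and smaller sets give fewer genes with a peak by construction. Counts of lists did not follow set size, with 14 lists from 4571 peaks and 5 from 5212; for these and the other changes the cause was not tested. Read depth is unknown, so its effect on weak sites cannot be given.

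Overlap of replicates was 51.1% within 50 bp, 73.9% by interval overlap of 1 bp and 57.3% with 2 times N. Optimal peaks found in all replicates numbered 2418 with the 4000 strongest of each and 2414 among the strongest 4001 when each replicate's list was cut to 4001 as well (3398 with N unchanged). Genes with a peak numbered 7080 at 5000 bp and 2288 with the strongest 4001, and lists past the threshold 7 with the latter and 2 with the background of genes with a pooled peak. Outside promoters 3 location classes passed the test, and introns (1.21) and other transcribed sequence (1.02) reversed, because the promoter share no longer enters. The GC box had an odds ratio of 0.542 unmatched, 0.563 against flanks (also not matched on G+C content) and 1.046 matched on location, and X 1.14 against sequence length and 1.19 by genes.

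Lists that reversed were, at 200 bp of a TSS, neuroblast factors (0.883) and salivary gland (0.674); at 1000 bp, salivary gland (0.981); at 5000 bp, Sp/KLF (0.970), insulin and TOR (0.970), neuroblast (0.831) and salivary gland (0.831). With the strongest 4001 peaks they were Sp/KLF (0.728), neuroblast (0.926), salivary gland (0.926) and proteasome (0.727), and with merged peaks Sp/KLF (0.873). On replicate 1 alone neuroblast gave 0.851, and on replicate 2 alone 0.719. On replicate 3 alone they were Hox (1.08), neuroblast (0.968), muscle (1.01), salivary gland (0.586) and proteasome (0.744). Against genes with a pooled peak they were Sp/KLF (0.532), cell cycle (0.709), neuroblast (0.710), muscle (2.13), fat body (0.399) and salivary gland (0.710).

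Words that reversed were, within 50 bp, E-box (0.807) and the reversed control (1.07); within 250 bp, TATA (1.09), Zelda (1.21) and Grainyhead (1.03); unmatched, E-box (0.786), TATA (1.64) and initiator (1.048). Against flanks, also not matched on G+C content, they were E-box (0.803), TATA (1.75), initiator (1.18) and GATA (1.16), and matched on location the extended GC box (1.06), E-box (0.876), Zelda (1.09) and the reversed control (1.21). With the strongest 4001 they were E-box (0.986), Zelda (1.15) and CTCF (0.702).

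Leaving out each replicate in turn gave ranges of 57.1 to 70.9% for overlap, 0.646 to 0.809 for rho, 2346 to 3226 genes with a peak and 5 to 14 lists past the threshold. The promoter odds ratio, 3.93 in the main result, was 2.48, 2.60 and 3.90 without replicates 1, 2 and 3. The background was redrawn with each smaller set and can include optimal peaks. A lower odds ratio of promoters or words therefore cannot be put down to the replicate left out alone. The odds ratios ranged over 0.706 to 1.42 for Sp/KLF, 0.604 to 1.28 for neuroblast, 0.772 to 1.48 for salivary gland and 0.706 to 1.66 for proteasome. Those of the Hippo, Notch and Polycomb lists were 3.31 to 3.85, 2.74 to 4.33 and 1.98 to 3.33. Words gave 1.53 to 2.64 for Ohler 1, 1.09 to 2.36 for TATCGATA, 0.885 to 1.03 for the GC box, 0.814 to 1.09 for its extended form, 1.07 to 1.69 for Zelda, 0.713 to 1.32 for CTCF, 0.317 to 1.31 for Grainyhead and 0.928 to 1.22 for the reversed control. X gave 0.920 to 0.984, and without replicate 3 it passed the test (Fisher's exact p = 0.0241).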

Other observations

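The tests of G+C content behind the rarer GC boxes and of other orders of the box's bases, and both tests of the region around Sp1 were chosen only after the result was seen; the other tests below were fixed before it.

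Some long genes held many optimal summits. The cell adhesion gene kirre had 32 (28.7 ± 4.73 in the replicates, SD, n = 3), the ecdysone-induced nuclear receptor gene Eip75B 31 (28.0 ± 5.29), Tet 28 (26.3 ± 2.08) and the transcriptional regulator gene sbb 28 (28.3 ± 4.16). Eip74EF with 17 and the receptor gene EcR with 15 were also among the 30 genes with the most summits, and no shared function of these genes was tested. Among these 30 genes the density was highest in Mnt, with 19 summits or 0.636 per kb. The longest of the genes named here, kirre, spans 394 kb and held 0.0812 summits per kb, not far above the 66.6 per Mb of X as a whole. These genes were chosen after their values were seen, and gene length was not corrected for.

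Among other gene classes, promoters of ncRNA genes had an optimal peak in 370 of 3261 cases (11.3%), tRNA genes in 31 of 290 (10.7%) and snoRNA genes in 24 of 269 (8.92%), all below the 27.8% of protein-coding genes. Pseudogenes had 12 of 268 (4.48%). None of 99 rRNA genes had a peak, with an upper Wilson bound of 3.74%, and reads shared between copies leave those calls uncertain. These differences were not tested.

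GC boxes were rarer at optimal summits than at background summits. Low G+C content fits as an explanation of this, since the interval of the odds ratio included 1 after matching (0.932, 0.799 to 1.09). The lack of an excess over background after matching held within 250 bp, with 0.931 (0.853 to 1.02). This argues against boxes off the summits being more frequent at optimal than at background peaks. Summits placed off the boxes in both sets stay open, since the background comes from the same pull-down. Box density near the summit over that farther out was 0.506 (0.425 to 0.595). This alone cannot be told apart from low G+C content, since the 5 other orders of the same bases gave 0.564. Relative to these orders the box density ratio was 0.896 (0.769 to 1.04). A box with a further G at either end also holds another of these orders, so an excess of boxes would raise them too. The value of 0.896 therefore cannot decide on an excess at summits. Recruitment by boxes, at many peaks or at few, stays open. Whether boxes mark stronger peaks at equal G+C content cannot be told apart from no effect, since the median signal ratio of 1.01 (0.907 to 1.12) has an interval that spans both. The intervals of 0.506, 0.896 and 1.01 come from 1000 bootstrap draws of optimal peaks and carry no spread between replicates. No biological explanation was tested.

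Replicate 3 had the lowest promoter share. Among the 2000 strongest peaks its gap to the mean of the others was 4.15 points, against 12.4 among the N strongest, a ratio of 0.334 (0.123 to 0.552), and weaker enrichment in this replicate could give such a ratio. Standardising its peaks to the G+C content of the others removed 31.6% of the gap (26.3 to 37.5) and left 8.5 points. The interval for G+C content lies wholly between the bounds set for and against it. G+C content could therefore account for a part of the gap, but short of the share set in its favour. The interval of the ratio reaches past the bound set in favour of weaker enrichment, so that explanation stays open. Both intervals come from 1000 bootstrap draws of peaks and carry no spread between replicates. No biological explanation was tested, as the replicates share 1 line and stage.

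Weak peaks were frequent around Sp1: the 100000 bp centred on its TSS held 34, 44 and 48 peaks weaker than the N strongest in replicates 1, 2 and 3, against medians of 19, 17 and 15 over windows of X. A further copy of the region carried by the tagged line could raise such counts, and it cannot be told apart from chance here, because the percentiles were 96.5 and 99.5 in replicates 2 and 3 and 97.6 in the pooled list, but 89.04 in replicate 1, with a counting range of 63.5 to 98.8. The 9 optimal peaks in the window lay at percentile 65.4 (41.9 to 94.7), which alone does not decide on shoulders of dense strong binding. No optimal summit lay between those at 9693990 and 9738695, yet weak pooled summits lay from 9699063 to 9736067. None lay between those at 9747662 and 9778731 either, with weak ones from 9756772 to 9773762. This spacing, looked at after the positions were seen, argues against shoulders as the source of these weak pooled peaks. No biological explanation was tested.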
